A study of Mus musculus with 6 samples.

How the data were processed

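Per the labels' protocols, total liver RNA was extracted with TRIzol, copied with SuperScript and made into libraries with Illumina protocols, and an Illumina HiSeq instrument read them. The strand setting of the libraries is not given in the sources used here. The 6 libraries were grouped by the genotype in the labels, 3 wild type and 3 Trim24 knockout. Read counts per gene symbol were deposited for each library, with no normalization, and the submitters' processing notes name TopHat 1.4.1, HTSeq, edgeR and the mm9 assembly without saying what each did. Each file held 23284 genes and 5 totals of the counter, of which only reads in no gene and ambiguous reads were above 0. Reads in no gene made up 93.3% to 95.8% of the counted reads and were left out of library sizes and tests. Ambiguous reads were 0.0130% to 0.0213%. No column was left unused (0), and 6295 genes were at 0 in all libraries.

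Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM factors and the group as the only term. Genes were kept by filterByExpr with a minimum count of 10, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 9180 tested genes. Log2 fold changes are knockout minus wild type, with standard errors taken as the change over the square root of F. CPM were computed on the reads in tested genes multiplied by the TMM factor of each library. Where a group had no count, the fold was given as a lower bound with 3 counts over the group in its place, and for 1 to 3 counts as a ratio with its exact 95% counting interval.

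The tests, the alternatives, the rule for named genes and 39 gene lists were fixed before the data were examined. The 32 lists with at least 5 tested genes, other than those only described, were tested two-sided with limma 3.58.1 camera on voom values with the preset correlation of 0.01, adjusted over the lists. For every list, adjusted p was also computed over the list alone. Named genes were Trim24, the 12 largest rises and 12 largest falls and the 6 smallest adjusted p, and up to 4 called members of each list, or 2 where none was called. A gene that this rule names is not reported here. For the largest rises and falls the groups had to be non-overlapping with a mean of at least 1 CPM in the higher group. Gene positions came from GENCODE M21 on GRCm38, to which 22791 of 23284 symbols (97.9%) were matched, 1909 of them through an older symbol. Since the notes name mm9, positions were used for chromosomes and distances only.

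Alternatives covered the scaling factors, the test (DESeq2 1.42.0, limma-voom and the edgeR exact test), the filter, the threshold, the replicate number as a block, each library left out, the correlation in camera, fry, and the window around Trim24. Further ones were added after seeing the data. With libraries left out the filter was applied anew, so the number of tested members of a list could differ. The per-gene test was tested on simulated counts for 9180 genes with 200 changed. It recovered 8.96% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 92.4% of those changed 4-fold. Of its 118 calls 11.0169% were false, above the share of 0.05 that the threshold aims at, in a single simulation. Whether the calls in the real data hold a like share of false ones was not tested. In simulated data without change the per-gene test called 0 genes and camera called 0 lists. Genes were simulated independently of each other, whereas interferon-stimulated genes had an estimated correlation of 0.51 in the real data. The 0 lists therefore do not measure false list calls among correlated genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.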

Results

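Liver RNA of 8-week-old mice of the C57BL6/J strain was sequenced in 3 libraries from wild type and 3 from homozygous Trim24 knockout liver. Trim24 encodes a member of the TIF1 family of nuclear receptor cofactors, and the title of the series places the mice in work on fat accumulation and cancer of the liver. The libraries are named WT1 to WT3 and KO1 to KO3 by the replicate number in the labels. Reads counted in genes came to 1495583, 1597540 and 1732309 in WT1, WT2 and WT3, and to 1607276, 1754269 and 2872421 in KO1, KO2 and KO3. These were 4.22% to 5.40% of all counted reads in the wild type libraries and 4.74% to 6.69% in the knockout libraries, so the usable depth was low. A count of 3, the upper limit that a count of 0 allows, corresponded to 2.10 CPM (counts scaled to 1e6 reads in tested genes and by the TMM factor) in WT1, and this limit covers counting error only. Albumin was the most abundant gene in WT1, with 8.51% of the reads in genes. Libraries correlated across genes at r = 0.958 to 0.965 within wild type, 0.957 to 0.959 within knockout and 0.917 to 0.945 between the groups, where genes are not independent replicates. The first principal component held 47.1% of the variance and separated the genotypes. The labels do not say whether the replicates came from separate mice, so the p-values measure the spread between these libraries.

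Trim24 itself checked the labels. Its counts were 31, 45 and 44 in WT1, WT2 and WT3, and 3, 2 and 2 in KO1, KO2 and KO3. This was 25.8 ± 4.1 CPM in wild type and 1.21 ± 0.59 CPM in knockout (SD, n = 3 each), a log2 fold change of -4.46 (SE 0.39, edgeR quasi-likelihood adjusted p = 2.1e-05). Reads outside a deleted part of the gene could remain in a knockout. The other tested members of its family were close to wild type, with Trim28 at 31.7 ± 3.3 and 34.2 ± 4.4 CPM and Trim33 at 63.0 ± 4.0 and 66.2 ± 5.4 CPM in wild type and knockout, and neither passed the threshold. Trim66 had a count of 0 in every library.

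The first comparison asked which liver genes differ between the genotypes. Of 9180 genes tested, 283 were higher and 243 lower in the knockout at an edgeR adjusted p under 0.05, and 193 and 106 of them changed at least 2-fold. The genes with the smallest adjusted p included Mug2, a plasma proteinase inhibitor of the alpha-macroglobulin family, which fell from 870 ± 75 to 16.8 ± 9.4 CPM (log2 fold change -5.61, SE 0.30, adjusted p = 2.3e-07). The gene 2410089E03Rik rose from 10.3 ± 1.8 to 136 ± 7.1 CPM (3.73, SE 0.19, adjusted p = 2.3e-07). D7Ertd143e fell from 72.3 ± 14.4 to 3.82 ± 0.94 CPM (adjusted p = 1.6e-06), and Mbd1, a reader of methylated DNA, rose from 84.1 ± 24.0 to 690 ± 82 CPM (adjusted p = 2.5e-06). Cyclin G1 (Ccng1) rose from 66.4 ± 2.1 to 261 ± 24 CPM (log2 fold change 1.97, SE 0.15, adjusted p = 9.6e-06). Mug2, 2410089E03Rik and Mbd1 each lie within 2 Mb of another gene changed over 4-fold, as described further below. Over all tested genes, 25% had groups that did not overlap, which chance gives for 10%.

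Among the 12 largest rises, Ccdc11 had no read in wild type and 57.7 ± 6.0 CPM in the knockout, at least 89.2-fold higher when set against 3 counts over the wild type group. Mep1a, a secreted and membrane metalloproteinase subunit, also had no wild type read and was at least 35.1-fold higher. The lipocalin gene Lcn13 rose from 1.94 ± 0.64 to 106 ± 73 CPM and the chemokine gene Cxcl1 from 4.57 ± 3.30 to 115 ± 84 CPM. Phlda3 had 1 wild type count against 74 knockout counts, a ratio of 54.1 with a counting interval of 9.41 to 2165. Tmigd1 and Gabra3 each had 2 wild type counts, with ratios of 32.5 (8.74 to 273) and 24.5 (6.52 to 206). Eda2r, Vwc2l, Gria3 and Slc13a5 reached 35.4 ± 14.5, 51.7 ± 34.4, 19.6 ± 8.0 and 22.4 ± 6.9 CPM in the knockout from 0.884 ± 0.446, 1.19 ± 2.06, 0.919 ± 1.071 and 1.56 ± 2.12 CPM, and Rpp40, a subunit of RNase P, rose from 3.42 ± 1.84 to 51.7 ± 11.5 CPM. Slc13a5 shares exon sequence with a gene on the opposite strand.

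Among the 12 largest falls, Rprl3 and St6galnac1 had no read in the knockout and were at least 33.8-fold and 20.1-fold lower against 3 counts over the group. Adh6-ps1 fell from 39.6 ± 20.9 to 4.27 ± 1.47 CPM, Mn1 from 21.5 ± 2.8 to 2.88 ± 2.08 CPM and Ugt3a1 from 74.2 ± 11.6 to 12.6 ± 1.9 CPM. Ppp1r3c, which targets protein phosphatase 1 to glycogen, fell from 122 ± 36 to 20.6 ± 11.1 CPM (log2 fold change -2.63, SE 0.31, adjusted p = 0.00032). Cyp2c39 fell from 123 ± 19 to 18.7 ± 25.7 CPM, a call that ended with DESeq2 (adjusted p = 0.23) and without WT2 or WT3 (0.051 for each), and Olfr541 fell from 11.9 ± 4.0 to 2.15 ± 1.89 CPM, a call that ended without WT2 (adjusted p = 0.072). Hcn3, at 128 ± 116 and 15.9 ± 4.8 CPM, overlaps Pklr on the opposite strand, and the 2 cannot be told apart in these counts.

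The number of calls depended on single libraries. Without WT1, WT2 or WT3, 175, 171 and 127 genes were higher and 143, 103 and 95 were lower, and without KO2 107 were lower. Of 114 named genes that passed the threshold, 47 lost it without at least 1 library, 42 of them without WT3. With DESeq2 the calls of H2-T23, Nsdhl, Fitm1, Tox, Icam1 and Dnajb1 also ended, and with limma-voom those of Hcn3, H2-T23, Tox and Top2a.

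**Figure D1:**
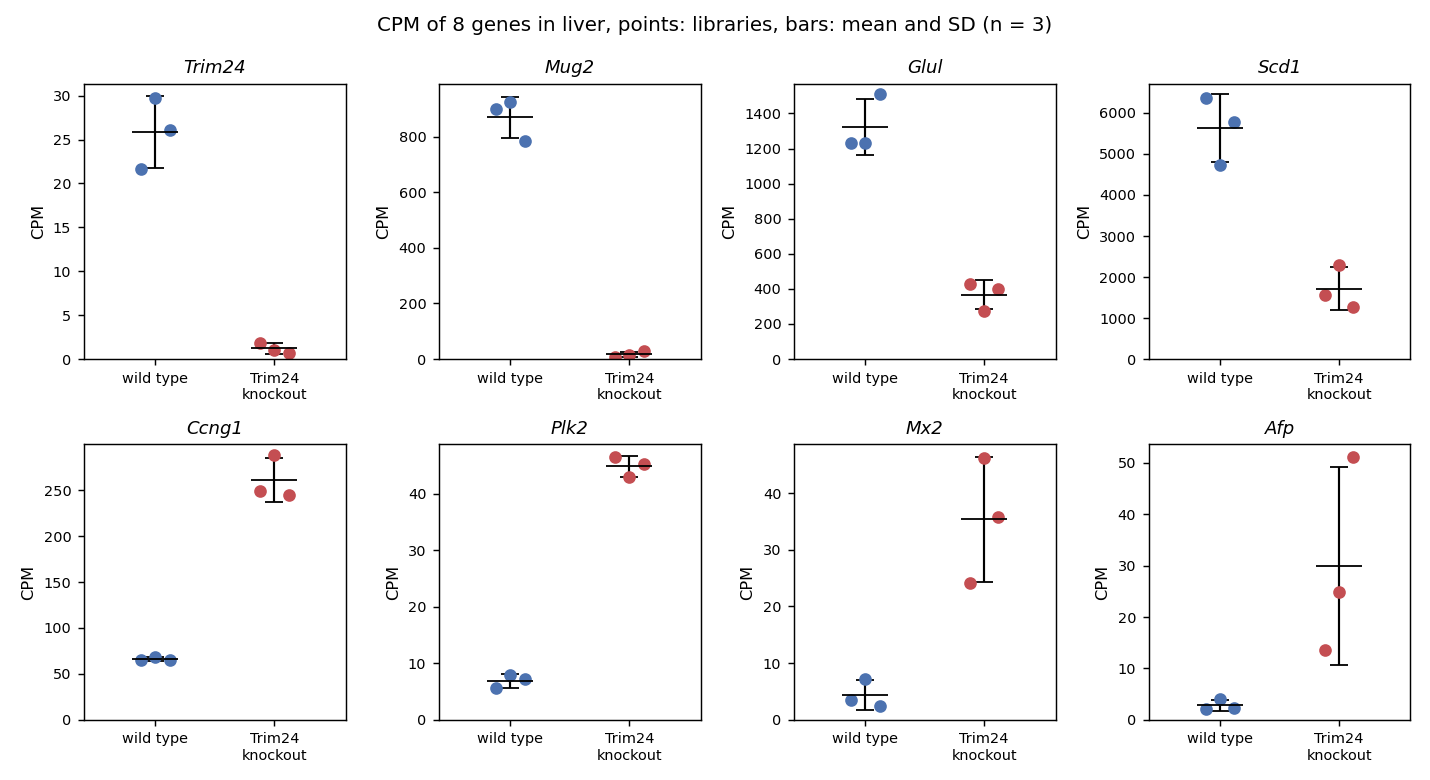
CPM (vertical axes, linear from 0) of 8 genes in each of the 6 liver libraries, with a point per library and bars for the group mean and SD (n = 3). Trim24, Mug2, Glul and Scd1 lie lower and Ccng1, Plk2, Mx2 and Afp higher in every knockout library than in any wild type library.

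Interferon-stimulated genes showed the broadest change of the lists fixed before the data were examined. Of 43 tested members 31 rose, none fell, and all 43 had a positive fitted change, with a median log2 fold change of 1.29 (39 rose when adjusted over the list alone). Mx2, an antiviral GTPase, rose from 4.38 ± 2.57 to 35.4 ± 11 CPM and Usp18, the protease that removes ISG15 from proteins, from 4.56 ± 0.37 to 34.9 ± 15.9 CPM (log2 fold change 2.94, SE 0.40, adjusted p = 0.00074). Ifi27l1 rose from 22.2 ± 3.1 to 133 ± 62 CPM and Ube2l6, the conjugating enzyme for ISG15, from 54.5 ± 5.3 to 124 ± 8 CPM. The list's limma camera adjusted p was 6.8e-26, and adjusted p = 0.27 with an estimated correlation. Without WT3, 16 of 50 tested members were called, and without KO1, the knockout library with the smallest shift, 39 of 50 were called. The median log2 difference from the wild type mean was 0.75, 1.46 and 1.39 in KO1, KO2 and KO3, and that of the Kupffer cell and macrophage markers was 0.23, 0.99 and 1.07. The markers lay at -0.38, 0.40 and 0.22 in WT1, WT2 and WT3, so KO1 was below WT2 for them. Of 16 antigen presentation genes, 2 rose, namely B2m (1351 ± 104 to 2196 ± 320 CPM) and H2-T23 (65.2 ± 7.2 to 103 ± 22 CPM), also when adjusted over the list alone. The camera adjusted p was 0.0046, and adjusted p = 0.27 with an estimated correlation, and no member was called without WT1, WT2 or WT3.

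**Figure D2:**
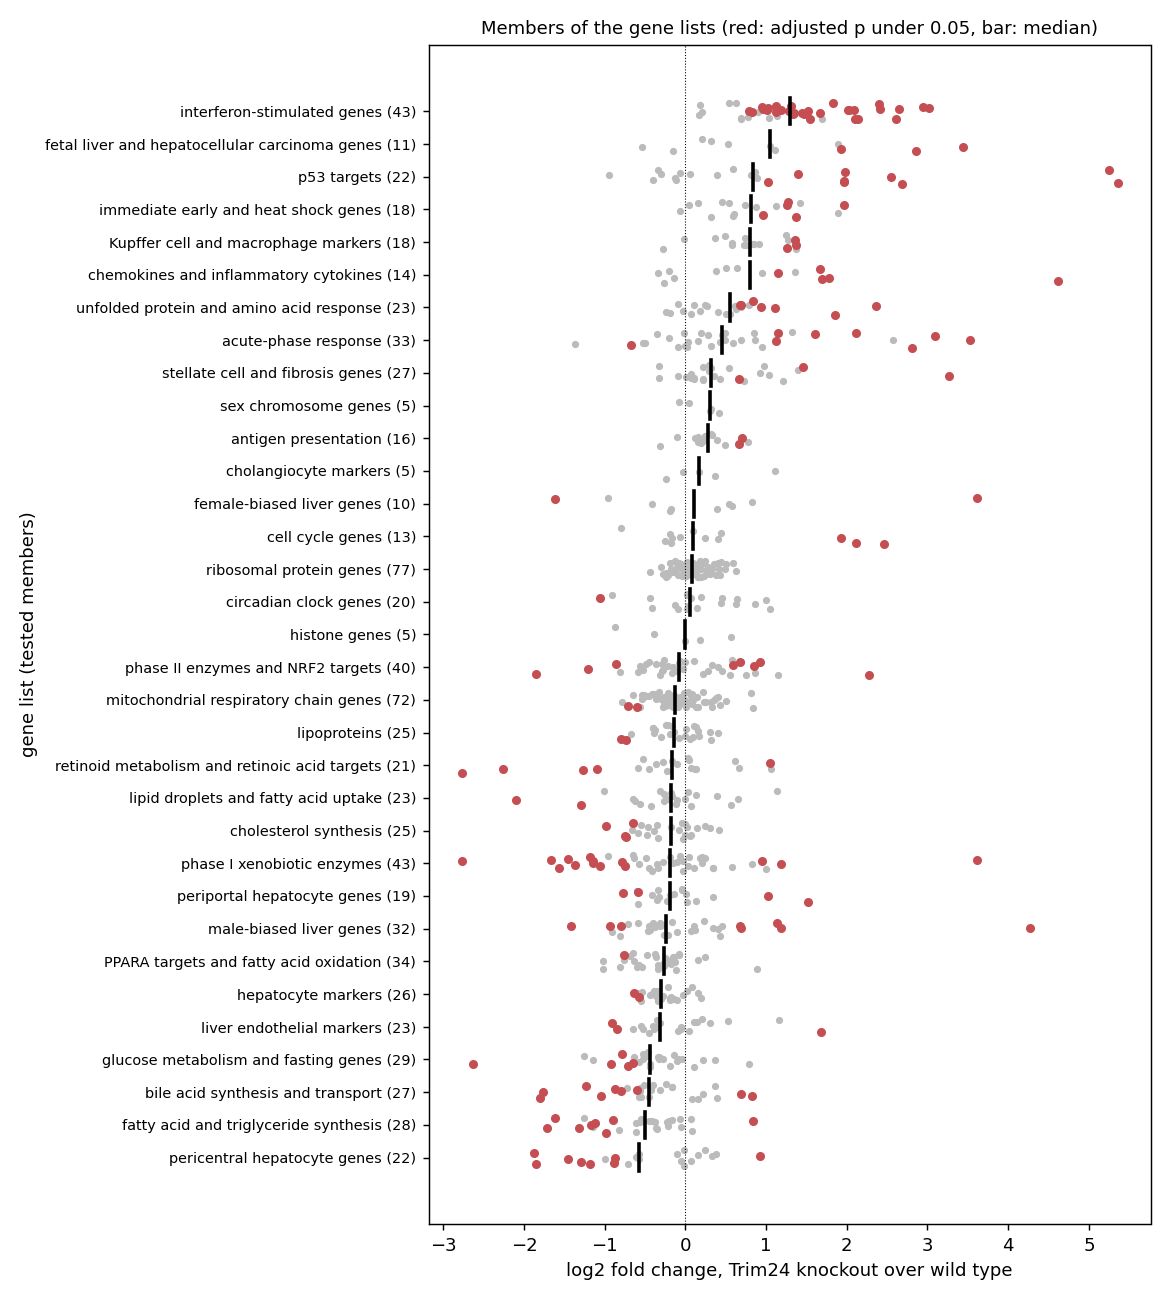
Log2 fold change of knockout over wild type (horizontal axis) for each tested member of the gene lists with at least 5 tested members (vertical axis, number of tested members in brackets), red where adjusted p was under 0.05 and grey otherwise, with a bar at the median. All 43 interferon-stimulated genes lie to the right of 0, and 25 of 28 fatty acid and triglyceride synthesis genes lie to the left.

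Targets of the tumour suppressor p53 rose in part. Of 22 tested members, 9 rose and none fell (12 rose and 2 fell when adjusted over the list alone). Besides Ccng1, Eda2r and Phlda3, the kinase gene Plk2 rose from 6.88 ± 1.19 to 44.8 ± 1.8 CPM (log2 fold change 2.69, SE 0.24, adjusted p = 2.3e-05). The camera adjusted p was 1.6e-06, and adjusted p = 0.18 with an estimated correlation. Between 8 and 10 members were called whichever library was left out. Genes of the unfolded protein and amino acid response followed, with 7 of 23 higher and none lower (10 and 0 when adjusted over the list alone, camera adjusted p = 2.1e-07, and adjusted p = 0.27 with an estimated correlation). Creld2 rose from 18.1 ± 8.3 to 65.2 ± 15.0 CPM, Manf from 91.9 ± 10.6 to 199 ± 38 CPM, the asparagine synthetase gene Asns from 12.5 ± 2.4 to 64.9 ± 42.3 CPM and Pdia6, which overlaps Atp6v1c2 on the opposite strand, from 182 ± 14 to 347 ± 59 CPM. Without WT2, 4 members were called. The unfolded protein list's median log2 difference from the wild type mean was 0.26, 0.47 and 0.60 in KO1, KO2 and KO3. Whether the pancreatic transcripts described below for KO1 and KO3 added to its rise was not tested. For both lists fry, which tests movement in a shared direction without comparing with other genes, also passed, with adjusted p = 0.0081 for p53 targets and 0.028 for the unfolded protein list.

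Of 18 immediate early and heat shock genes, 5 rose and none fell (14 and 0 when adjusted over the list alone, camera adjusted p = 6.6e-08, and adjusted p = 0.27 with an estimated correlation). The chaperone gene Hsp90aa1 rose from 316 ± 44 to 758 ± 140 CPM, Btg2 from 19.7 ± 5.3 to 75.5 ± 37.3 CPM and Klf6 from 24.8 ± 4.8 to 63.8 ± 20.6 CPM. Btg2 is also among the p53 targets that rose. Dnajb1 rose from 13.4 ± 3.3 to 26.1 ± 1.7 CPM, a call lost without WT1, WT3, KO2 or KO3 (adjusted p up to 0.15, without WT3). Without WT1, WT3 or KO2, 3 members were called, and without KO1 9. Of 11 tested genes of fetal liver and hepatocellular carcinoma, 3 rose and none fell (4 and 0 when adjusted over the list alone, camera adjusted p = 0.0016, and adjusted p = 0.38 with an estimated correlation). Afp, the fetal counterpart of albumin, rose from 2.81 ± 1.01 to 29.9 ± 19.2 CPM (log2 fold change 3.44, SE 0.53, adjusted p = 0.0018), S100a11 from 2.76 ± 1.42 to 20.5 ± 5.9 CPM and the cyclin D1 gene Ccnd1, which overlaps Oraov1 on the opposite strand, from 19.6 ± 9.7 to 74.0 ± 35.3 CPM. Without KO1, 5 were called. Ccnd1 is also among the 3 of 13 cell cycle genes that rose (3 and 0 when adjusted over the list alone), with Mki67 (4.15 ± 1.25 to 17.3 ± 8.8 CPM) and Top2a (2.67 ± 2.02 to 13.8 ± 9.4 CPM). That list was not called (camera adjusted p = 0.14, and adjusted p = 0.58 with an estimated correlation), and 1 member was called without WT2, WT3 or KO3. With the filter of at least 1 CPM in 3 libraries it was called higher (camera adjusted p = 0.0017).

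Some markers of macrophages and of inflammation rose, with wide spread. Of 18 Kupffer cell and macrophage markers, 3 rose and none fell (10 and 0 when adjusted over the list alone, camera adjusted p = 3.7e-06, and adjusted p = 0.38 with an estimated correlation). The complement gene C1qc rose from 10.6 ± 4.6 to 27.2 ± 6.5 CPM, Mpeg1 from 32.9 ± 9.8 to 84.3 ± 41.0 CPM and Ctss from 25.3 ± 11.2 to 60.9 ± 18.5 CPM. No marker was called without WT1 or WT3, 1 without KO2 or KO3, and 9 without KO1. Of 14 chemokine and cytokine genes 5 rose, including Cxcl1, Vcam1 (32.2 ± 9.4 to 71.9 ± 21.8 CPM), Icam1 (3.87 ± 1.95 to 13.2 ± 4.0 CPM) and Cxcl9 (6.27 ± 4.41 to 19.7 ± 4.5 CPM), and none fell (6 and 0 when adjusted over the list alone). The camera adjusted p was 0.0034, and adjusted p = 0.30 with an estimated correlation. Without WT3 only Cxcl1 was called, with 2 members called without WT1 or KO2 and 3 without WT2 or KO3. Cxcl9 is also on the list of interferon-stimulated genes. Of 33 acute-phase genes 7 rose and 1 fell (9 and 3 when adjusted over the list alone, camera adjusted p = 0.00064, and adjusted p = 0.48 with an estimated correlation). Steap4 rose from 212 ± 19 to 644 ± 204 CPM, Saa3 from 2.13 ± 0.82 to 15.7 ± 4.0 CPM, Serpina3n from 632 ± 233 to 1396 ± 356 CPM and the interleukin 1 receptor gene Il1r1 from 82.7 ± 10.5 to 181 ± 69 CPM. Without WT3, 2 acute-phase genes were called higher, without WT1 or KO2 3, and without KO1 11, while none fell without WT2, WT3 or KO3. The acute-phase median difference from the wild type mean was 0.15, 0.61 and 0.15 in KO1, KO2 and KO3. It was -0.15, 0.32 and -0.17 in WT1, WT2 and WT3, so WT2 lay above KO1 and KO3. Of 3 tested neutrophil markers, Csf3r rose (3.03 ± 1.39 to 9.87 ± 3.20 CPM), a call that ended with each library left out other than KO1 (adjusted p up to 0.18, without WT3), with DESeq2 (0.15) and with limma-voom (0.072). No lymphocyte marker passed the expression filter.

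Of 27 stellate cell and fibrosis genes, 3 rose and none fell (6 and 0 when adjusted over the list alone, camera adjusted p = 0.00052, and adjusted p = 0.42 with an estimated correlation). The collagen genes Col5a2 and Col1a2 rose from 3.02 ± 2.03 to 29.9 ± 17.4 CPM and from 8.78 ± 1.74 to 24.4 ± 9.1 CPM, and decorin (Dcn) from 232 ± 7 to 366 ± 47 CPM. Without WT1, WT2 or KO2 only Col5a2 was called of these, without WT3 or KO3 2 members were called, and without KO1 8. The stellate list's median difference from the wild type mean was 0.004, 0.63 and 0.37 in KO1, KO2 and KO3. Liver endothelial markers went both ways, with 1 higher and 2 lower of 23 (2 and 4 when adjusted over the list alone, camera adjusted p = 0.060, and adjusted p = 0.46 with an estimated correlation). Tek, an angiopoietin receptor, rose from 33.2 ± 1.6 to 106 ± 17 CPM (log2 fold change 1.68, SE 0.17, adjusted p = 9.5e-05), while the scavenger receptor gene Stab2 fell from 119 ± 6 to 63.1 ± 18.7 CPM and Ehd3 from 72.9 ± 6.4 to 40.8 ± 9.0 CPM. Neither fall was called without WT3 (adjusted p = 0.065 and 0.097), and 1 was without WT1, WT2 or KO2. None of 5 tested cholangiocyte markers passed, at 3.48 ± 3.29 and 7.56 ± 3.57 CPM for Cd24a and 19.9 ± 3.6 and 25.3 ± 4.1 CPM for Pkhd1 in wild type and knockout (camera adjusted p = 0.36, and adjusted p = 0.67 with an estimated correlation). That list was called higher with the filter of at least 1 CPM in 3 libraries (0.017), and the endothelial list was called lower with it (0.038) and without WT1 or KO3 (0.021 and 0.014). Adrb3 was the 1 of 3 tested adipocyte genes that rose (1.57 ± 1.66 to 11.1 ± 5.5 CPM), a call lost without WT1, WT3 or KO2 (adjusted p = 0.092, 0.097 and 0.094). Neither tested red blood cell gene passed, with Alas2 at 148 ± 11 and 146 ± 35 CPM and the beta globin gene Beta-s at 43.5 ± 11.2 and 41.6 ± 4.5 CPM.

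Transcripts of pancreatic acinar cells were present in KO1 and KO3. The 20 listed genes summed to 921 CPM in KO1 and 607 CPM in KO3, against 24.4, 5.29 and 1.19 CPM in WT1, WT2 and WT3 and 2.71 CPM in KO2. Prss2, a trypsinogen gene, had 246 and 266 counts in KO1 and KO3 and 1 in KO2. None of these genes passed the filter in the comparison of all 6 libraries, and 15 were called higher without KO2. With KO2 as the only knockout library, 301 genes were higher and 268 lower, and 326 of the 526 calls were kept, while 1 had the opposite sign and 243 other genes were called. That fit was chosen after seeing the data and assumes that the single library varies like the wild type ones. In it 29 interferon-stimulated genes, 8 p53 targets, 8 Kupffer cell markers and 8 stellate cell genes were called higher. Not called in it were H2-T23, Fitm1, Lipc, Scarb1, Cyp2b9, Cyp2u1, Tox, Icam1, Cxcl9, Tdo2, Cebpa, Agxt2l1, Pigr, Mki67, Top2a, Ppp1r3b, Dnajb1 and Cox7c.

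**Figure D3:**
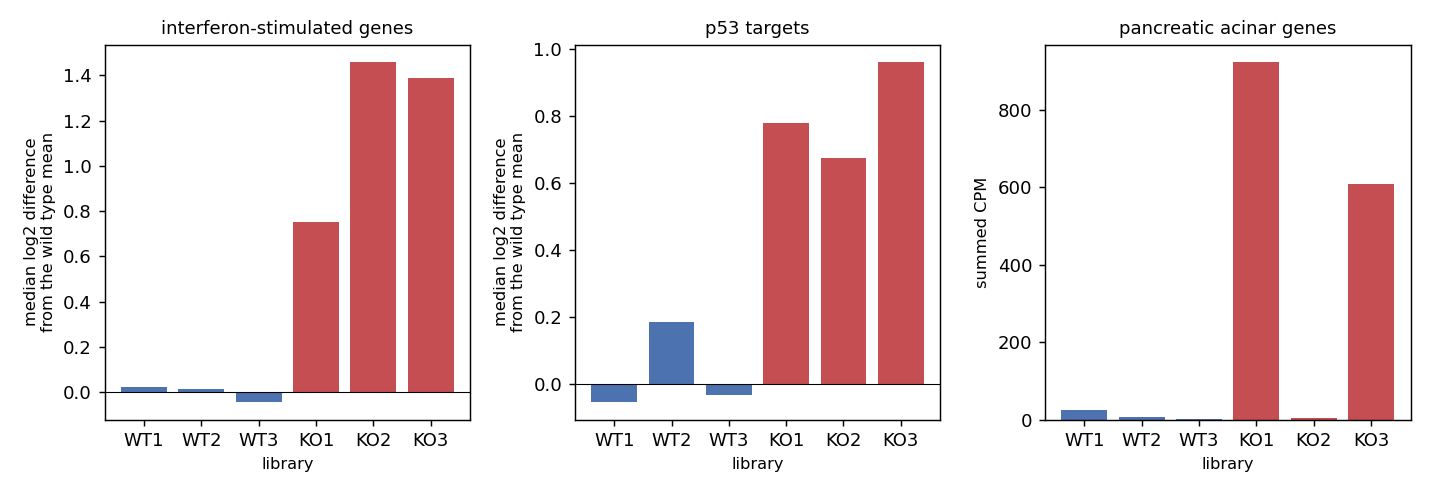
Median log2 difference from the wild type mean over the 43 interferon-stimulated genes and over the 22 p53 targets, and summed CPM of the 20 pancreatic acinar genes (vertical axes, linear), for each library (horizontal axis, wild type blue, knockout red). KO2 has 1.46 for interferon-stimulated genes and 0.67 for p53 targets with 2.71 CPM of pancreatic transcripts.

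Some genes of lipid synthesis fell. Of 28 fatty acid and triglyceride synthesis genes 7 fell and 1 rose (13 and 1 when adjusted over the list alone, camera adjusted p = 6.6e-08, and adjusted p = 0.27 with an estimated correlation). Scd1, the stearoyl-CoA desaturase of liver, fell from 5624 ± 829 to 1713 ± 529 CPM (log2 fold change -1.71, SE 0.21, adjusted p = 0.00041). The malic enzyme gene Me1 fell from 129 ± 12 to 52.0 ± 10.3 CPM, the acetyl-CoA synthetase gene Acss2 from 224 ± 53 to 72.9 ± 19.3 CPM and the elongase gene Elovl5 from 573 ± 32 to 262 ± 47 CPM. Me1 and Acss2 overlap genes on the opposite strand, among them Gss for Acss2. The number that fell was 5 to 8 across the fits with libraries left out, and the rise was called in none of them but that without KO1. Of 25 cholesterol synthesis genes 4 fell and none rose (4 and 0 when adjusted over the list alone, camera adjusted p = 0.0064, and adjusted p = 0.55 with an estimated correlation), by 1.67-fold for Cyp51, 1.68-fold for Sc5d, 1.98-fold for Tm7sf2 and 1.57-fold for Nsdhl. None was called without WT3 or KO2, and 1 without WT2. Cyp51 overlaps Akap9 on the opposite strand. The list was not called without WT3 or KO2 (camera adjusted p = 0.13 and 0.14), and its median difference from wild type was -0.15, -0.55 and 0.02 in KO1, KO2 and KO3.

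Lists for the use, storage and transport of lipids held fewer calls. Of 34 PPARA targets and fatty acid oxidation genes 1 fell and none rose, and none passed when adjusted over the list alone. Of the 34, 31 had a negative fitted change, and the camera adjusted p was 0.00012, and adjusted p = 0.48 with an estimated correlation. No member fell without WT2, WT3, KO2 or KO3, and 6 fell without KO1. The median difference from the wild type mean was -0.07, -0.63 and -0.16 in KO1, KO2 and KO3, and the list was not called without KO2 (camera adjusted p = 0.053). Of 23 lipid droplet and uptake genes 2 fell, the droplet coat gene Plin5 (40.6 ± 12.5 to 16.9 ± 4.8 CPM) and Fitm1 (8.78 ± 1.74 to 1.73 ± 1.53 CPM), and 4 when adjusted over the list alone (camera adjusted p = 0.043, and adjusted p = 0.38 with an estimated correlation). Neither was called without WT2, WT3 or KO2, 1 was without WT1, and without KO1 2 members rose. The list was not called without WT2, KO1 or KO2 (camera adjusted p = 0.062, 0.054 and 0.082). Of 25 lipoprotein genes 2 fell, also when adjusted over the list alone, namely the hepatic lipase gene Lipc (181 ± 23 to 104 ± 3 CPM) and the high-density lipoprotein receptor gene Scarb1 (102 ± 19 to 61.3 ± 4.6 CPM), and the list was not called (camera adjusted p = 0.052, and adjusted p = 0.38 with an estimated correlation). The lipoprotein list was called lower without KO3 (0.0095) and with the filter of at least 1 CPM in 3 libraries (0.037). Scarb1 was not called without WT2, WT3 or KO2 (adjusted p = 0.11, 0.060 and 0.088).

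Some of the genes that mark hepatocytes around the central vein fell. Of 22 tested pericentral genes 7 fell and 1 rose (10 and 1 when adjusted over the list alone, camera adjusted p = 7.4e-05, and adjusted p = 0.35 with an estimated correlation). Glul, glutamine synthetase, fell from 1324 ± 159 to 367 ± 81 CPM (log2 fold change -1.85, SE 0.19, adjusted p = 8.0e-05), the ornithine aminotransferase gene Oat from 763 ± 78 to 312 ± 29 CPM and the glutamate transporter gene Slc1a2 from 364 ± 75 to 100 ± 34 CPM. Rgn rose from 1416 ± 122 to 2697 ± 109 CPM. Glul overlaps 5830403L16Rik on the opposite strand. Between 6 and 9 members fell whichever library was left out. Of 19 periportal genes 2 rose and 2 fell (2 and 3 when adjusted over the list alone, camera adjusted p = 0.22, and adjusted p = 0.55 with an estimated correlation). Hsd17b6 rose from 133 ± 18 to 379 ± 62 CPM and Aldh1b1 from 37.8 ± 8.1 to 76.7 ± 13.9 CPM, while Agxt2l1 fell from 124 ± 22 to 73.2 ± 12.9 CPM and Pigr from 927 ± 25 to 617 ± 89 CPM. Neither fall was called without WT2, WT3 or KO3, and Aldh1b1 was not called without WT2 (adjusted p = 0.053), while the periportal list was called lower without WT1 (camera adjusted p = 0.035). Of 26 general hepatocyte markers 2 fell, Tdo2 (3007 ± 511 to 1940 ± 109 CPM) and the transcription factor gene Cebpa (170 ± 16 to 114 ± 13 CPM), and 4 when adjusted over the list alone. The camera adjusted p was 5.9e-05, and adjusted p = 0.38 with an estimated correlation, and none was called without WT2, WT3, KO2 or KO3, 1 without WT1, and 5 without KO1.

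Of 29 genes of glucose metabolism and fasting 5 fell and none rose (9 and 0 when adjusted over the list alone, camera adjusted p = 6.1e-06, and adjusted p = 0.27 with an estimated correlation). With Ppp1r3c these included the glucose-6-phosphate transporter gene Slc37a4 (237 ± 44 to 125 ± 40 CPM), the glucose transporter gene Slc2a2 (393 ± 60 to 229 ± 59 CPM) and Ppp1r3b (220 ± 40 to 135 ± 29 CPM). Without WT3, KO2 or KO3 1 member was called, and without WT1 2. Of 27 bile acid genes 7 fell and 2 rose (14 and 2 when adjusted over the list alone, camera adjusted p = 1.2e-05, and adjusted p = 0.38 with an estimated correlation). The exporter gene Abcc3 fell from 358 ± 52 to 105 ± 30 CPM (log2 fold change -1.77, SE 0.21, adjusted p = 0.00034), Slco1a4 from 70.0 ± 21.6 to 20.7 ± 6.4 CPM, Cyp27a1 from 445 ± 34 to 244 ± 47 CPM and the bile acid uptake gene Slc10a1 from 1156 ± 192 to 562 ± 164 CPM. Without WT3 and WT2, 3 and 4 members fell, and without KO1 11, and none rose without WT3 and 1 without WT1, WT2, KO1 or KO3. Cyp27a1 and Slc10a1 were not called without WT3 (adjusted p = 0.060 and 0.053), nor Slc10a1 without WT1 (0.053).

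Of 43 phase I xenobiotic enzymes 11 fell and 3 rose (14 and 4 when adjusted over the list alone, camera adjusted p = 0.00093, and adjusted p = 0.48 with an estimated correlation). Cyp2e1 fell from 6708 ± 176 to 2955 ± 974 CPM, Cyp2c38 from 66.6 ± 13.2 to 21.9 ± 9.3 CPM and the carboxylesterase gene Ces1e from 179 ± 12 to 69.4 ± 28.8 CPM. Cyp2b9 had 3 wild type and 57 knockout counts, a ratio of 13.9 (counting interval 4.52 to 69.3). Without WT2, WT3 or KO2, 7, 5 and 7 members fell, and without KO1 5 rose. Of 40 phase II enzymes and NRF2 targets 5 rose and 3 fell (6 and 5 when adjusted over the list alone). Gstp2 rose from 10.7 ± 2.7 to 51.5 ± 15.5 CPM and the epoxide hydrolase gene Ephx1 from 179 ± 16 to 339 ± 36 CPM, while Ugt1a1, which conjugates bilirubin, fell from 275 ± 39 to 120 ± 28 CPM and Gstm6 from 368 ± 9 to 203 ± 37 CPM. The list was not called (camera adjusted p = 0.99, and adjusted p = 0.99 with an estimated correlation), and its median and mean differed in sign (-0.05 and 0.04 on the voom scale). Without WT2, WT3 or KO3, 3 rose. Of 21 genes of retinoid metabolism and retinoic acid targets 4 fell and 1 rose (5 and 2 when adjusted over the list alone, camera adjusted p = 0.043, and adjusted p = 0.35 with an estimated correlation). The retinol dehydrogenase genes Rdh16 and Rdh11 fell from 123 ± 15 to 57.5 ± 12 CPM and from 94.1 ± 19.4 to 38.2 ± 14.5 CPM, Cyp2c39 fell as given above, and Tgm2, transglutaminase 2, which overlaps Rprd1b on the opposite strand, rose from 58.4 ± 4.5 to 120 ± 33 CPM. Without WT3 only Rdh16 of these kept its call, with adjusted p = 0.052 for Rdh11 and 0.059 for Tgm2, and 2 members fell without WT2. The retinoid list was not called without WT2, WT3, KO1 or KO2 (camera adjusted p = 0.067, 0.16, 0.12 and 0.22), nor with the filter of at least 1 CPM in 3 libraries (0.068). Many of these enzymes have close paralogs, among which the deposited counting may divide reads.

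All 6 libraries had reads from Y-linked genes, with Ddx3y at 171 ± 22 and 212 ± 29 CPM and Eif2s3y at 81.7 ± 8.6 and 109 ± 2 CPM in wild type and knockout, none of which passed the threshold, and Xist was at 21.0 ± 8.5 and 26.3 ± 17.3 CPM. Male-biased liver genes went both ways, with 5 higher and 3 lower of 32 (5 and 4 when adjusted over the list alone, camera adjusted p = 0.22, and adjusted p = 0.63 with an estimated correlation). Nox4 fell from 83.8 ± 5.8 to 43.9 ± 6.0 CPM and Slco1a1 from 928 ± 33 to 534 ± 102 CPM, while Cyp2u1 rose from 31.6 ± 3.4 to 71.4 ± 19.4 CPM and the urinary protein gene Mup21 from 176 ± 20 to 387 ± 169 CPM. Slco1a1 and Mup21 were not called without WT2 (adjusted p = 0.051 and 0.077) or WT3 (0.060 and 0.087), and 1 member rose without WT3, 2 without WT1 and 3 without WT2 or KO3, while 1 fell without WT2 or WT3. Of 10 female-biased genes Cyp2b9 rose and Tox fell (8.33 ± 1.92 to 2.68 ± 0.47 CPM), and 1 rose and 2 fell when adjusted over the list alone. Tox was not called without WT1, WT2, KO2 or KO3 (adjusted p = 0.062 to 0.13) and did not enter the test without WT3, and 2 members rose without WT1, WT2 or WT3 and 3 without KO1. The list was not called (camera adjusted p = 0.70, and adjusted p = 0.77 with an estimated correlation), and its voom median of -0.05 and mean of 0.20 differed in sign. Nnt, part of which is deleted in C57BL/6J mice, was at 93.8 ± 4.2 and 128 ± 35 CPM, and the groups overlapped.

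The remaining lists changed little. Of 20 circadian clock genes Nr1d1, which overlaps Thra on the opposite strand, fell (55.8 ± 13.3 to 26.6 ± 2.8 CPM, not called without WT1, adjusted p = 0.057), and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.49, and adjusted p = 0.74 with an estimated correlation). None of 77 ribosomal protein genes passed by edgeR, over all genes or adjusted over the list alone, with Rps21 at 23.4 ± 2.5 and 36.0 ± 2.9 CPM and Rps23 at 39.4 ± 5.5 and 59.0 ± 11.3 CPM (camera adjusted p = 0.11, and adjusted p = 0.74 with an estimated correlation). Without KO1 the ribosomal list was called higher (0.0091) with 1 member called. Of 72 respiratory chain genes Cox7c (73.1 ± 5.2 to 44.6 ± 1.8 CPM) and Sdhb (138 ± 8 to 91.4 ± 12.4 CPM) fell, 1 when adjusted over the list alone, and neither was called without WT1, WT2, WT3 or KO2 (camera adjusted p = 0.043, and adjusted p = 0.60 with an estimated correlation). The respiratory chain list was not called without WT1, WT3 or KO2 (0.067, 0.073 and 0.36). None of 5 tested histone genes passed, with Hist1h1e at 14.0 ± 8.9 and 7.78 ± 2.25 CPM and Hist2h2bb at 8.57 ± 2.41 and 12.4 ± 4.0 CPM (camera adjusted p = 0.79, and adjusted p = 0.87 with an estimated correlation).

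In all, the preset-correlation camera test called 10 lists higher and 11 lower of 32, and with an estimated correlation it called none. Only the p53 and unfolded protein lists passed by fry.

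The last comparison asked whether called genes gather near Trim24, as alleles carried along with a modified locus would. Trim24 lies on chromosome 6 in the GENCODE M21 annotation of GRCm38. Within 20 Mb to each side, 9 of 116 tested genes (7.76%) were called, against 508 of 8981 (5.66%) elsewhere, an odds ratio of 1.403 (two-sided Fisher's exact p = 0.31). The 9 genes were D630045J12Rik, Exoc4, Gimap4, Herc6, Inmt, Parp12, Pdia4, Ppm1k and Tmem176b.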

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

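The alternatives that removed genes overlapping a gene on the opposite strand, thinned all libraries to equal depth or kept KO2 as the only knockout library were chosen after seeing the data. Trim24 stayed lower in all 18 refits, with log2 fold changes from -4.83 to -4.09 and adjusted p of 0.00042 or less. The 283 higher and 243 lower genes became 278 and 243 with RLE factors, 309 and 225 with upper-quartile factors, 228 and 252 with DESeq2, 234 and 239 with limma-voom and 383 and 355 with the edgeR exact test. They became 118 and 67 at adjusted p under 0.01, by construction, and 576 and 509 with no filter on low counts, where 16989 genes were tested. A fold change of at least 1.5 left 277 and 239. With 1 library left out, 127 (without WT3) to 409 (without KO1) genes were higher and 95 (without WT3) to 363 (without KO1) were lower, with fewer samples in each fit. Of the 526 calls, 206 were kept without WT3, 251 without WT2, 266 without KO2 and 475 without KO1. With overlapping genes removed 255 and 212 were called, with thinned libraries 271 and 228, and with KO2 alone 301 and 268.

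The 10 higher and 11 lower lists became 0 and 0 with an estimated inter-gene correlation and 2 and 0 with fry. For p53 targets and antigen presentation genes the estimated correlations were 0.0051 and -0.024, below the preset 0.01. Their unadjusted camera p still rose, from 2.5e-07 to 0.0057 and from 0.0024 to 0.031. A higher correlation therefore does not account for the lost calls of these lists. In limma the estimated setting also takes its degrees of freedom from the libraries, and the preset one from the genes. The part of this difference was not tested separately. With at least 1 CPM in 3 libraries 13 of 34 lists were higher and 12 lower. The replicate block ended the lipid droplet call and added the lipoprotein and endothelial lists. With KO2 alone the lipoprotein, male-biased, endothelial and periportal lists were also called lower. With 1 library left out, 10 to 11 lists were higher and 6 (without KO2) to 13 (without KO3) were lower. With the replicate number as a replicate block, 295 genes were higher and 250 lower, and 10 lists were higher and 12 lower. As deviations from the mean of their own group, samples sharing a number correlated at -0.0731, 0.0789 and 0.0349, so the numbers were not taken as pairs. The share of called genes near Trim24 was 6.06% within 10 Mb, 7.65% within 40 Mb and 8.62% with the replicate block. Nsdhl and Cebpa lost their calls with upper-quartile factors, H2-T23 and Tox with the replicate block, H2-T23 with at least 1 CPM in 3 libraries, and Nsdhl, Fitm1 and Sdhb with thinned libraries. Sex as a covariate was not run, since all libraries had reads from Y-linked genes. At the observed depth with 3 libraries per group, the simulated counts recovered 8.96% of 1.5-fold and 56.7% of 2-fold changes. Depth was not varied there, so its part in this was not tested.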

Other observations

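The tests of opposite-strand counting, missing chromosomes, pancreatic tissue, alleles linked to Trim24 and both sets of neighbouring genes were chosen only after related results were seen. The imprinted genes Meg3, Rian and Rtl1, named after their values were seen, lie together on chromosome 12 in GENCODE M21 on GRCm38, and all rose. Meg3 went from 1.76 ± 0.50 to 16.4 ± 7.4 CPM (log2 fold change 3.24, SE 0.49, edgeR adjusted p = 0.0016), Rian from 1.78 ± 1.06 to 12.3 ± 5.7 CPM and Rtl1 from 1.08 ± 1.39 to 8.24 ± 2.09 CPM. Mug1, a close paralog of Mug2 also named after its values were seen, fell from 12115 ± 715 to 7197 ± 934 CPM (adjusted p = 0.012).

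The real grouping called 526 genes and 21 lists. Each other of the 10 splits called 0 genes. Their list calls ran from 3 (WT1, KO1 and KO3 against the rest) to 19 (WT1, WT3 and KO1 against the rest). For genes and for lists, 1 of the 10 splits had as many calls, the real one, and 10 splits are too few for a share under 0.05.

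Few reads were assigned to genes in every library. Against chromosomes missing from the counting, 0 of 20 chromosomes lacked reads in genes. For counting on the strand opposite to the transcripts, the gene outside the lists had the higher count in 31.8% of 44 pairs, between the bounds set for and against it. Snx22, for example, lay at 2415 ± 306 and 2677 ± 441 CPM where its opposite-strand neighbour Ppib lay at 280 ± 15 and 294 ± 71 CPM, both named after their values were seen. In the 44 pairs whole-gene counts were compared for overlaps of at least 100 bases, so reads outside an overlap also entered. The share therefore cannot decide the question. The strand setting stays open, and for genes with such an overlap the transcript that changed cannot be told apart from its neighbour.

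Of 22 tested p53 targets 9 rose, and each of the 9 lay above the wild type mean in all 3 knockout libraries. This follows largely from their being called, since 521 of all 526 called genes had non-overlapping groups. Against a single knockout library as the cause, at least 9 members were called whichever knockout library was left out. Against pancreatic tissue in KO1 and KO3, the 9 members called in the fit without KO2, chosen without its values, had a median log2 difference from wild type of 2.10 in KO2 (1.03 to 4.76), beside 1.89 in KO1 and 2.42 in KO3. Over all 22 the median in KO2 was 0.67. The genotype, and any other difference between the groups of mice, stays open and was not tested.

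Of 89 genes changed over 4-fold, 67 rose and 22 fell. Some lay within 2 Mb of another, such as Mbd1 and Ccdc11 on chromosome 18 and 2410089E03Rik and Ugt3a1 on chromosome 15. Mug2 and Usp18 on chromosome 6 and Afp and Cxcl1 on chromosome 5 did so too. For alleles of another strain linked to Trim24, 0 of the 89 genes other than Trim24 lay within 20 Mb of it. That window held 116 tested genes against 8981 elsewhere, so chance alone would place few there. The 0 therefore cannot count against linked alleles. For blocks of another strain's alleles elsewhere in the genome, 40.2% of the 87 with a position had another within 2 Mb, against a mean of 20.6% in random sets (permutation p = 0.0009999). Neighbouring genes of one family or one list did not account for all of this, since with listed genes removed and 1 gene kept per symbol stem the permutation p was 0.0211. There 49 genes were left, and 26.5% of them had a neighbour against a mean of 12.4% in random sets. With neighbouring genes that share reads across strands and the imprinted locus of Meg3 also removed, 41 genes were left, 19.5% of them had a neighbour against 9.88% in random sets, and the permutation p was 0.0810. With fewer genes left, the higher p does not show that the removed neighbours made up the excess. Blocks of another strain's alleles and such neighbours therefore cannot be told apart, and the genotype stays open.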
